A study of Rattus norvegicus with 8 samples.

How the data were processed

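RNA was measured from the livers of 8 Wistar rats aged 21 days, 4 born to dams on a standard diet (control) and 4 born to dams on a diet without vitamin B12 and folate (methyl donor deficient). Per the labels, the dams were on the diet from before pregnancy until the pups were weaned. Replicates were numbered by the order of the samples within a group, and these numbers do not pair animals. Each animal is a separate sample per the labels. Dams and litters were not given in the sources used here. The titles carry letter and number codes of unstated meaning, in which 3 controls share a letter and 2 deficient animals share another, so that littermates may be among the replicates and the p-values measure the spread between these animals only.

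Each deposited file holds 1 Agilent 2-colour rat array with spot intensities, extracted with Agilent Feature Extraction 10.7.1.1 per the file headers. The 8 samples lie on 4 arrays of 1 slide scanned on 1 day, so that slide and scan day were not batches. The labels give the dye of each sample, and samples were assigned to the same array where their deposited array data were identical. Every array so carries 1 control and 1 deficient sample in different dyes. The deficient sample is in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4. Array 1 pairs control replicate 1 with deficient replicate 3, array 2 pairs control 3 with deficient 1, array 3 pairs control 2 with deficient 4, and array 4 pairs control 4 with deficient 2. Probe positions are those of the rn4 build in the files, with chromosomes and starts as the files give them. The authors also deposited a table of normalized intensities on a linear scale, whose normalization is not given in the sources used here. Its medians per sample lie between 183.8 and 192.5, and its values track the log2 mean signal of each sample's own channel (r from 0.9945 to 0.9995). It was used only as an alternative.

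The values were computed with limma 3.58.1 in R 4.3.3. Mean signals were corrected for their local background with normexp (offset 50), normalized by loess within each array with control spots at weight 0, and made comparable between arrays with Aquantile. Before normexp, spots whose local background was over 5 times the median background of their channel were left out, 74 spot values in all. This step was added after results without it had been seen. On array 3 a few spots had local backgrounds up to 67824.5 in control replicate 2 and 257955 in deficient replicate 4, against medians of 57 and 36. They drove the noise SD that normexp estimates to 1130 and 2980, while it lay between 1.9 and 9.3 in the other channels, and the SD of that array's log2 ratios was 0.237 with the spots kept against 0.399 without them. Without the spots the noise SD was between 1.84 and 6.72 in every channel. The threshold was set from the background values alone, after several thresholds had been looked at, and the results with these spots kept are in the closing section.

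Spots marked as outliers by the software were then left out, the spots of a probe were averaged, and a probe was kept if it was well above background in at least 4 of the 8 samples. Of the probes of a gene the brightest was used. Of the 232 called genes with several probes measured, 216 had all probes in the same direction. Besides 1377 control spots, each file holds 42877 spots that stand for 30367 probes. Gene symbols are those of the files, updated through the RefSeq table for 3795 probes, and 9602 probes have no symbol. Of the 14863 genes tested, 10514 have a symbol. Between 59.1% and 65.5% of the spots were well above background, no spot was saturated, and the small number of arrays limits the precision.

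Diet was tested with limma's lmFit and eBayes over the 8 samples, with diet and dye as terms and the array as a block (estimated correlation 0.422), and p-values were adjusted by Benjamini-Hochberg at 0.05. Sex was tested in the same fit with sex added, and a diet by sex term was fitted once more. The array correlation could not be estimated in some fits with few samples (females only, and sex with an array left out), where that of the 8 samples was used. Gene lists of pathways and cell types were fixed before the data were examined. The 31 lists with at least 5 measured members were tested with camera (preset inter-gene correlation 0.01) on values with the array correlation removed. An estimated correlation, fry and ranks were alternatives.

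The genes named follow a rule fixed before the data were examined: the 12 largest rises and 12 largest falls among called genes with a symbol and the same direction on all 4 arrays, up to 4 members of each list with the smallest p, and a set of genes named in advance. Of these last, probes of Dnmt1 and Esr1 were not well above background in enough samples to be tested, and Sirt1 was not analysed here. Another of the genes named in advance is not reported here. Genes named from the lists beyond this rule were chosen after their values were seen. Coordinates are given for a few of the named genes.

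On simulated data with the same 8 samples and 14863 genes, the fit called 55.2% of 67 genes changed by 0.5 in log2, 98.5% of 67 genes changed by 1 and 100% of 66 genes changed by 2, with 17 false calls. The simulated genes were drawn independently of each other, so these numbers do not give the error of the fit on the measured data. For the lists, 3 of 3 simulated shifts of 0.5 were called with 0 false calls. This does not describe the error of the list test on the measured data, where estimated inter-gene correlations reached 0.78 and camera called 1 to 12 lists in each of the 33 other fitted splits of the samples. Alternatives covered background correction, normalization, filters, probes per gene, the dye term, the block, sex, females only, the eBayes options, the deposited normalized table, each replicate and each array left out, and the list tests. Those chosen after seeing the data are sample weights, the spots in very high local background kept, and a correlation held fixed in 1 fit for sex.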

Results

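The study measured liver gene expression at weaning in pups of rat dams fed a standard diet or a diet lacking vitamin B12 and folate, the nutrients that supply methyl groups through the methionine cycle. There were 4 control and 4 deficient animals, 1 of the control and 2 of the deficient animals being male. Each array compared 1 animal of each group. Median spot signals lay between 152.5 and 299 over backgrounds of 33 to 58, and between 59.1% and 65.5% of the spots were well above background. Fold changes below are log2 values, deficient minus control, with the SE of the fit over n = 4 animals in each group, and the adjusted p-values of genes are from limma.

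The question of the diet comparison was which liver genes differ between pups of deficient and control dams. In livers of the deficient pups 12 of 30 genes of fatty acid beta-oxidation rose, while 16 of 25 genes of cholesterol synthesis, 12 of 24 of glutathione and NRF2 targets and 11 of 24 acute phase genes fell. The largest rise was that of Acot1, an acyl-CoA thioesterase, by 4.42 ± 0.62 (limma adjusted p = 0.00504). Cpt1b, the muscle isoform of the enzyme that carries fatty acids into mitochondria, rose by 3.72 ± 0.32, Igfbp1, a binding protein for insulin-like growth factors, by 3.11 ± 0.43, and Tnnc2, troponin C of fast skeletal muscle, by 2.85 ± 0.19. Ldhb rose by 2.71 and Fgf21, a hormone secreted by liver in fasting, by 2.31 ± 0.28. The largest falls were those of Serpina3c (-2.93 ± 0.38), Hamp, which encodes the iron hormone hepcidin (-2.73 ± 0.36), Thrsp, a regulator of fatty acid synthesis (-2.60 ± 0.36), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.58 ± 0.31).

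In all, 1648 of 14863 genes tested were called by limma, 672 higher and 976 lower in deficient livers. At an unadjusted p under 0.05 there were 4110, where chance would give 743. Of the called genes 249 changed by more than 2-fold, 108 higher and 141 lower. The median over all genes was 0.01. Among the other large rises were Dusp26 (2.61), Mt2A (2.50), Fabp2 (2.48), Fst (2.49) and Hdc (2.40), the last 2 losing their call with some replicates left out. Aqp3, a channel for water and glycerol, rose by 2.68 but was well above background in only 1 control. The other large falls were Gsta2, Car3, Igfals, Gsta5, Ces1d, Sez6, Srd5a1 and Gpx1, between -2.29 and -1.90. A second probe of Sez6 was at -0.11 and not called. The probes for Acot1, Cpt1b, Igfbp1 and Cyp7a1 lie in rn4 on chromosome 6 from 108049691 to 108049750, on chromosome 7 from 127737188 to 127737247, on chromosome 14 from 87954736 to 87954795, and on chromosome 5 from 19707410 to 19707469. The 4 arrays differed in the spread of their ratios. The SD of the within-array ratios was 0.312 on array 1, 0.574 on array 2, 0.399 on array 3 and 0.42 on array 4. Over genes not called it was 0.269, 0.465, 0.285 and 0.317, so array 2 was also the widest there. Deficient replicate 1, on array 2, had the lowest sample weight (0.306). Across genes, ratios on array 1 correlated at 0.42 with those of array 3, which has the same dye orientation. They correlated at 0.094 and 0.15 with those of arrays 2 and 4, which have the other. Arrays 2 and 4, of the same orientation, correlated at 0.63. Arrays 2 and 3, and arrays 3 and 4, of opposite orientations, correlated at 0.6 and 0.64. The low values were thus those of array 1, not of opposite orientation as such. Genes are not independent replicates. With the spots in very high local background kept, as first processed, 953 genes were called. The number was 208 without array 3, 41 in females only (3 control, 2 deficient animals), 1665 without deficient replicate 3, and 1134 without array 1.

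**Figure D1:**
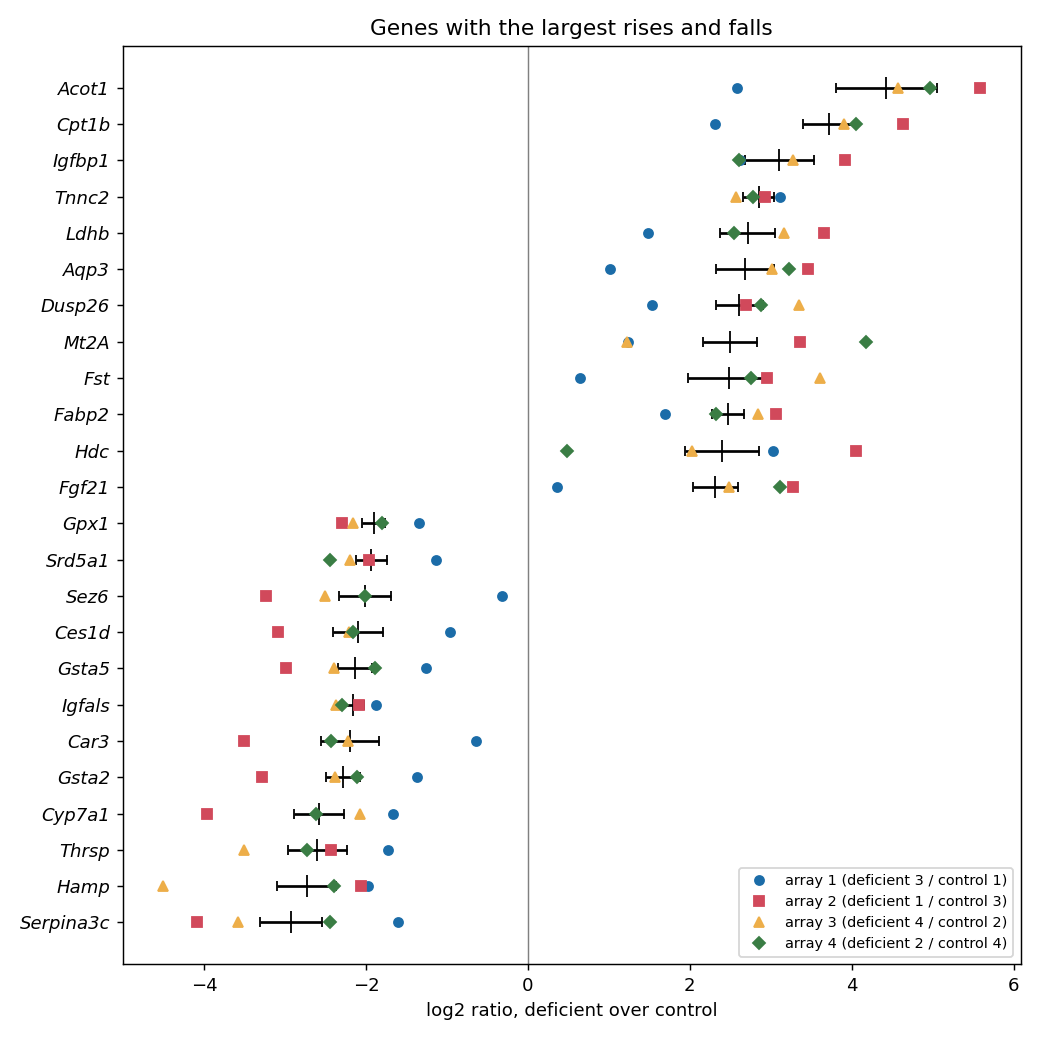
Log2 ratio of deficient over control on each of the 4 arrays (coloured symbols, 1 pair of animals per array) for the 12 genes with the largest rise and the 12 with the largest fall; black bars mark the fitted change and its SE. Array 1 lay nearest to 0 for most of these genes, while Tnnc2 was between 2.57 and 3.12 on every array.

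Some fatty acid oxidation genes rose. Of 30 genes of beta-oxidation measured, 12 rose, 1 fell and 17 were not called, and of 19 targets of the nuclear receptor PPARalpha 8 rose and 0 fell. Cpt1a, which controls the entry of fatty acids into mitochondria, rose by 1.46 ± 0.23, Ehhadh by 1.74 ± 0.27, Acot2 by 1.88 ± 0.33, Vnn1 by 2.23 ± 0.19 and Acot3 by 1.36 ± 0.18. The lists were called with camera at adjusted p-values of 2.38e-05 and 2.47e-05. With an estimated correlation the adjusted p = 0.465 for beta-oxidation and adjusted p = 0.45 for the PPARalpha targets, so the calls were lost. Beta-oxidation also lost its camera call in 2 of 32 settings, and directional fry did not call it (fry adjusted p = 0.096). Adjusted over the list alone, 17 and 12 of their genes were called, 16 and 11 of them higher and 1 lower in each. Neither Ppara (0.06 ± 0.14, limma adjusted p = 0.831) nor Ppargc1a (0.34 ± 0.10, limma adjusted p = 0.075) passed the test. Oxidative phosphorylation, called up by camera (adjusted p = 0.0268, adjusted p = 0.465 with an estimated correlation), had 4 of 51 genes rising, namely Ndufa2, Ndufs4, Ndufa5 and Cox7a2, by 0.31 to 0.40. It had 0 genes called adjusted over the list alone, lost its camera call in 8 of 32 settings, and without array 1 had 0 genes rising (camera adjusted p = 0.151). Without array 3, 2 beta-oxidation genes and 4 PPARalpha targets rose.

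Most of the measured cholesterol synthesis genes fell. Of 25 genes measured 16 fell and 0 rose, with a median of -0.88, among them Dhcr7 (-1.61 ± 0.28), Fdft1 (-0.71 ± 0.11) and Ebp (-0.67 ± 0.11). Adjusted over the list alone, 22 were called. The list was called down by camera at adjusted p = 2.54e-12, and with an estimated correlation the adjusted p = 0.45. Sqle (-1.82) and Srebf2 (-0.73), the transcription factor that drives the pathway, also fell. In fatty acid and triglyceride synthesis 8 of 20 fell and 2 rose, without a call for the list (camera adjusted p = 0.0711). Pklr fell by 1.45 and Acly by 1.04, whereas Elovl2, which elongates polyunsaturated fatty acids, rose by 1.73 ± 0.25. Srebf1 was at 0.06 ± 0.22 (limma adjusted p = 0.895). Of 18 genes of bile acid synthesis and transport 4 fell, Cyp7a1, the bile acid uptake transporter Slc10a1 (-1.04 ± 0.09), Baat (-0.77) and Slco1a1 (-0.78), and the list was not called (camera adjusted p = 0.0908). Without array 3, 0 cholesterol synthesis genes fell, although the list was called (camera adjusted p = 2.32e-11), and 2 genes of fatty acid synthesis and 2 of bile acids fell, with both lists called (camera adjusted p = 0.0157 and 0.0323). With an estimated correlation and without array 3, none of these 3 lists was called (camera adjusted p = 0.422 for each). Without array 1, 10 cholesterol synthesis genes fell.

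The folate and methionine cycle, which the diet addresses directly, fell in part. Of 41 genes measured 11 fell and 1 rose, and 18 were called when adjusted over the list alone. Aldh1l1, which oxidises a folate one-carbon unit in the cytosol, fell by 1.11 ± 0.14, Shmt2 by 0.68 ± 0.09, Sardh by 0.93 ± 0.15, Bhmt, which remethylates homocysteine from betaine, by 0.85 ± 0.21, and Cbs, which removes homocysteine, by 0.47 ± 0.08. Aldh1l2, the mitochondrial counterpart of Aldh1l1, rose by 0.55 ± 0.08. The list was called by camera at adjusted p = 2.47e-05, and with an estimated correlation the adjusted p = 0.45. Without array 3, 2 of its genes fell and 0 rose. Mtr, the methionine synthase that uses both missing vitamins, was at -0.01 ± 0.08 (limma adjusted p = 0.958). Its probe was well above background in only 3 controls and 2 deficient animals, so a change could have been missed. The reductase of Mtr, Mtrr, was at -0.21 ± 0.21 (limma adjusted p = 0.547), and neither gene was called. Gnmt (-0.34 ± 0.14) and Mat1a (-0.25 ± 0.29) were also not called. In cobalamin uptake and processing 2 of 13 genes rose, Abcc1 (0.42 ± 0.11) and the cobalamin receptor Cd320 (0.29 ± 0.08), without a call for the list (camera adjusted p = 0.42). Each of these 2 genes kept its call in only 2 of the 12 settings with a replicate or array left out, and Bhmt in 3. None of the 19 genes of DNA and histone methylation was called, with 3 at an unadjusted p under 0.05 in limma (0 called adjusted over the list alone; camera adjusted p = 0.767). In this list 2 genes fell without deficient replicate 3, 1 fell without array 1 and 1 rose without deficient replicate 1. Of 23 genes in the list of nuclear receptors and coregulators, Esrra (0.47 ± 0.07), Nr1h2, Ppargc1b and the transcription factor Nrf1, which is neither, rose. Nr1h4, the bile acid receptor, fell by 0.82 ± 0.15 (camera adjusted p = 0.519 for the list). Without array 3, 0 of these 23 genes rose or fell. With a replicate or array left out, Ppargc1b kept its call in 3 of 12 settings, Nr1h2 in 5 and Nr1h4 in 8, and a second probe of Nr1h4 was at -0.34 and not called. Hnf4a was at -0.16 ± 0.10 (limma adjusted p = 0.333).

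Transcripts of the growth hormone and insulin-like growth factor axis shifted in both directions. Igf1 fell by 1.33 ± 0.16, Igfals, which keeps it in the circulation, by 2.16 ± 0.13, Prlr by 1.07 ± 0.13 and Ghr by 0.98, whereas the binding proteins Igfbp1 and Igfbp2 (2.30 ± 0.15) rose. Of 16 genes 5 fell and 2 rose, and the list as a whole was not called (camera adjusted p = 0.213). Of 23 genes of the urea cycle and amino acid catabolism 6 rose, among them Sds (2.14 ± 0.33) and Asl (1.12 ± 0.16), and 7 fell, among them Glud1 and Arg1. In glucose and insulin signalling 2 of 20 genes rose, Gys2 (1.06 ± 0.19) and Igfbp1, and 5 fell, among them Slc2a2 (-0.55) and Gckr (-0.59). The targets of ATF4, which responds to amino acid shortage, had 5 of 21 rising, including Trib3 (2.26 ± 0.34), Atf3 (1.33) and Pck2 (0.98), and Psat1 falling by 1.16. These last 3 lists were not called, with camera adjusted p-values of 0.672, 0.518 and 0.0954. Without array 3, 3 genes of the growth hormone axis fell, 1 gene of the urea cycle list and 1 of the glucose list rose with 0 falling in either, and 2 ATF4 targets rose. Without array 1 the ATF4 list was called (camera adjusted p = 0.0289, adjusted p = 0.614 with an estimated correlation). It was also called without deficient replicate 1 (camera adjusted p = 0.0467, adjusted p = 0.453 with an estimated correlation).

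Of 24 NRF2 and glutathione genes 12 fell and 2 rose, with Gsta2 (-2.29 ± 0.21), Gsta5 (-2.13 ± 0.21) and Aox1 (-1.62 ± 0.16) in the lead. Of 19 genes of the unfolded protein response 7 fell, among them Dnajb11 (-0.43) and Manf (-0.63), and 0 rose. Of 24 acute phase genes 11 fell and 1 rose, including Cp (-1.05 ± 0.08 on its brightest probe, with 1 of 2 other probes at 0.59), Fga (-0.98), Fgb (-0.74 ± 0.08) and Hamp. Of 35 cell cycle genes 14 fell and 0 rose, including Tk1 (-0.85 ± 0.15), Aurka (-0.90 ± 0.16) and Ccna2 (-0.66 ± 0.14), with a median of -0.51. The 4 lists were called by camera at adjusted p-values of 0.000271, 2.47e-05, 0.000154 and 1.13e-10, and each had an adjusted p = 0.45 with an estimated correlation. Adjusted over the list alone, 14, 12, 14 and 25 genes were called. Without array 3, 3 NRF2 genes and 3 acute phase genes fell, and 0 genes of the unfolded protein response or of the cell cycle. Without array 1, 5 cell cycle genes fell. Among the lists with no call, 3 p53 targets rose, Gadd45b (1.18 ± 0.15), Btg2 and Zmat3, and 2 fell, Ei24 (-0.58) and Sesn1 (-0.47; camera adjusted p = 0.213). Without array 3, 1 p53 target rose and 0 fell, and without deficient replicate 1, 2 rose and 0 fell. The 16 imprinted and fetal liver genes had 0 calls by limma and 4 at an unadjusted p under 0.05, and Igf2 was at -1.80 ± 0.64 (limma adjusted p = 0.109; camera adjusted p = 0.672 for the list). Without deficient replicate 1, 2 of these genes fell and 0 rose.

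**Figure D2:**
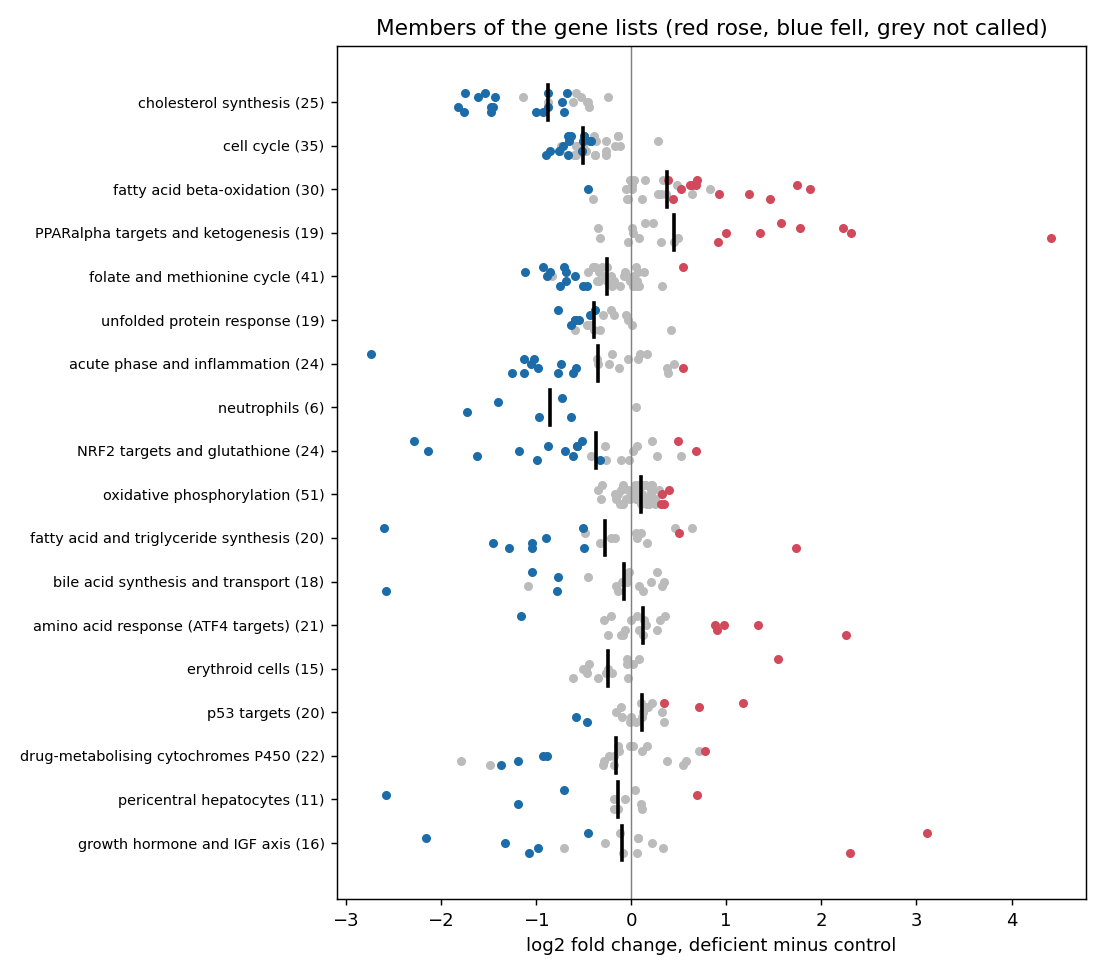
Log2 fold change, deficient minus control, of each measured member of 18 gene lists (1 point per gene; the number of members in parentheses), red for genes that rose, blue for genes that fell and grey for genes not called; black bars mark the list median. Cholesterol synthesis had a median of -0.88 and PPARalpha targets one of 0.45.

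Markers of other cell types were measured alongside. Of 6 neutrophil transcripts 5 fell, with S100a9 at -0.97 ± 0.13, S100a8 at -0.72 ± 0.11 and Defa5 at -1.72 ± 0.28 (camera adjusted p = 0.000264, adjusted p = 0.45 with an estimated correlation). Lists for erythroid cells (camera adjusted p = 0.128), lymphocytes (0.333), Kupffer cells (0.672), endothelial cells (0.672), stellate cells (0.515), cholangiocytes (0.672) and pericentral (0.213) and periportal (0.754) hepatocytes were not called. The pancreas and the adipose and muscle lists had under 5 measured members and were not tested. Among 15 erythroid genes only Tfrc, the transferrin receptor, was called, and it rose by 1.55 ± 0.23. The median of that list was -0.237, with 1 gene higher and 4 lower at an unadjusted p under 0.05 in limma. Skeletal muscle transcripts stood apart on array 1, which carries deficient replicate 3: of 16 abundant ones, a list written after values were seen, 12 were higher by 1 or more in log2 on array 1, with a median of 2.10, against medians of 0.09, 0.19 and -0.07 on arrays 2, 3 and 4. Of the 16, 9 did not pass the filter on background, so their ratios are imprecise. Over the other 7 the median was 2.12 on array 1, and 0.127, 0.242 and -0.083 on arrays 2, 3 and 4. Tnnc2 was higher on every array, by 3.12, 2.93, 2.57 and 2.78. Without deficient replicate 3, 16 cholesterol synthesis genes and 12 acute phase genes fell and 15 beta-oxidation genes rose. Without array 3 these counts were 0, 3 and 2, and 3 neutrophil transcripts fell. Without array 1, 1 erythroid gene rose and 4 fell, and that list was called (camera adjusted p = 0.00483, adjusted p = 0.614 with an estimated correlation). The count of lists called by camera, 10 of 31, is not specific to diet, as 8 of 34 splits of the samples, the diet split included, gave as many.

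**Figure D3:**
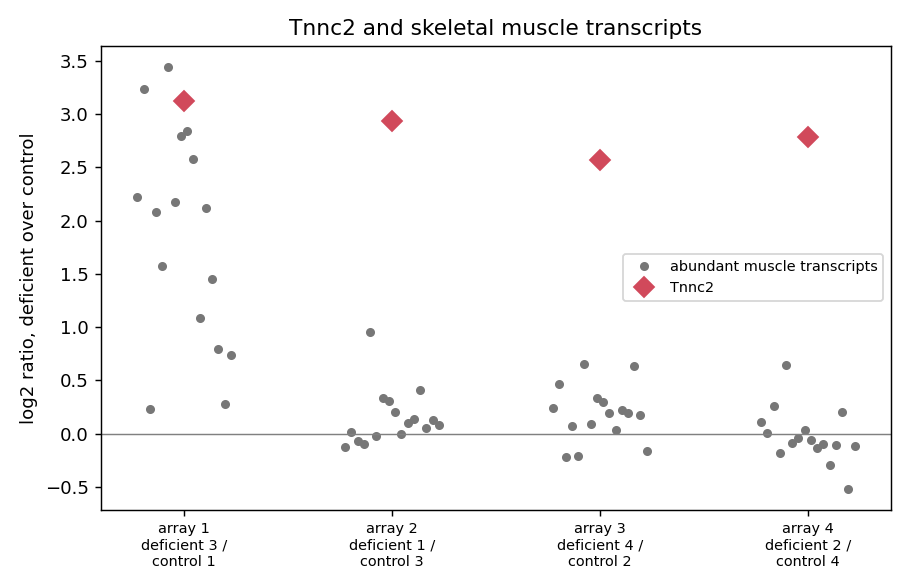
Log2 ratio of deficient over control on each array for 16 abundant skeletal muscle transcripts (grey points, 9 of them below the background filter) and Tnnc2 (red diamonds), 1 pair of animals per array. On array 1, which carries deficient replicate 3, the median of the grey points was 2.10; on arrays 2, 3 and 4 the medians were 0.09, 0.19 and -0.07.

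The sex of the animals, 3 male and 5 female, was tested in the fit with diet. No gene was called by limma (0 of 14863, with 400 at an unadjusted p under 0.05, where chance would give 743), and the smallest adjusted p was 0.313, for Hbb-bs. Limma called 340 genes for sex without deficient replicate 2, 74 without array 1, 7 without control replicate 1, 11 with loess only, 3 on within-array ratios with a dye term and 120 with sample weights, a setting added after results were seen. Without deficient replicate 1 it called 6639, which became 0 when the array correlation of the 8 samples was kept. The diet by sex term gave 0 called genes by limma, with a smallest adjusted p of 0.0706. It had 1786 genes at an unadjusted p under 0.05, where chance would give 743, unlike the 400 for sex. The term rests on 1 male control, so it can neither show nor exclude an interaction. With sex in the fit, limma called 824 genes for diet, 814 of them shared with the fit without it. Labels of sex could not be checked on Y-linked genes or Xist, since of 10 such genes only Sry had a probe and its values did not separate the sexes. The X-linked Utx lay at log2 8.452 to 8.711 in females and 7.791 to 8.003 in males, and Eif2s3 at 11.71 to 11.96 and 11.19 to 11.52, so both parted the animals as the labels do. These genes were chosen after their values were seen.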

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

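All tests of explanations in this part were chosen after the results were seen, except that of the spiked-in transcripts. In 24 of 314 groups of 4 animals, 1 animal lay far from the other 3. Chance would give about 15.7 if the groups were independent. Most of the genes were picked from these data and related genes are not independent, so the 24 cannot be weighed against that number. Deficient replicate 3 was that animal for 11 genes, and these were nearer to control levels or, for muscle and collagen genes, higher. The ratio of its gap to the range of the group was 0.869 for Acot1, 0.904 for Cpt1b, 0.903 for Aqp3, 0.869 for Cyp7a1, 0.903 for Dnmt3b, 0.933 for Ehhadh, 0.87 for Acot2, 0.862 for Vnn1, 0.921 for Asl, 0.906 for Col1a2 and 0.844 for Tnni2. Acot1 was at log2 10.24 in this animal and 14.03 to 14.6 in the other deficient animals, and Tnni2, a fast muscle troponin, at 11.5 against 8.041 to 8.58.

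Other deficient animals lay apart for Cox7a2 (0.859), Fga (0.957) and Cyp2d2 (0.836), all in deficient replicate 1, and for Zmat3 (0.862) and Bhmt (0.878), in deficient replicate 2. Among controls, control replicate 1 lay apart for Igf2bp2 (0.843), Cyp2c22 (0.866) and Mtr (0.878), control 2 for Aqp3 (0.89), and control 4 for Ces1d (0.895), Dnmt3b (0.913) and Aqp1 (0.836). The median signal of deficient replicate 2, in Cy5, was 299 against 152.5 to 158.5 in the other deficient samples (0.959).

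The first pattern is the small diet difference on array 1, whose ratios had a slope of 0.182 on those of the other arrays. Exchanged labels on this array are argued against, as 75.5% of the 1134 genes called without it went the same way on it. The same check gave 92%, 100% and 89% for arrays 2, 3 and 4. On array 1 the ratios of those genes were a median of 0.314 of the fold changes fitted without it. A compressed signal in the scanned intensities is argued against as well, as the slope of 10 spiked-in transcripts was 1.01, against 0.99 to 1.01 on the other arrays. The spiked-in ratios were taken before normexp, loess and Aquantile, so compression that arises in these steps was not tested. A sex difference common to both diets did not account for it, since the slope was 0.236 with the fitted sex difference taken off. Array 1 carries the 1 male control, so a sex difference that depends on diet cannot be told apart from that animal. Such a difference was not taken off in the sex test. That last test replaced an earlier version over called genes, which could hardly fail, and differences between dams, litters or the animals' exposure may remain as an untested biological explanation.

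The second pattern is Tnnc2. Muscle carried over with the tissue is a candidate explanation in deficient replicate 3, where the median of the muscle transcripts was 2.1. Of the 9 that did not pass the background filter, 8 were well above background in this animal. In control replicate 1, on the same array, 4 of them were, against 0 or 1 in each other control. The signal may thus not be confined to deficient replicate 3, which was not tested. Carried-over muscle is argued against in deficient replicates 1, 2 and 4, where the median of the muscle transcripts was 0.0775 and the highest of the 16 reached 0.957, below Tnnc2 on every array. Over the 7 of them that passed the background filter the median there was 0.14 and the highest 0.656. The muscle genes were split by array after their values were seen, and the rise of Tnnc2 in those 3 animals stays as a hypothesis of liver expression or of the probe binding another transcript, neither of which was tested.

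The third pattern is the number of called genes. For diet, 1 of 34 splits of the samples, the real one, gave as many (1648, with 19 the highest of the others). Only 7 of the 34 part every array as the real one does (highest other 0), too few for a share under 0.05. The remaining splits place both samples of an array in the same group, unlike the real one, so chance is not excluded for this count. Chance cannot be excluded for the lists, as 8 of 34 splits, the real one included, gave 10 or more (highest other 12). For sex the test decides nothing, since 56 of 56 splits give at least the real count of 0 by construction. The highest other split gave 720, and the cause was not tested. The larger share of males among deficient animals is argued against as the cause of the diet genes, as their fold changes with sex in the fit were 0.982 of those without it (median; quartiles 0.941 and 1.02).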

How the results depend on the processing

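The number of genes called for diet depended on the processing, although 109 of 109 called named genes kept their direction in every setting run. Against 1648, there were 307 with median centring in place of loess, 839 without a dye term, 465 and 383 on within-array ratios with and without a dye term, 395 without the block, 824 with sex as a term, 41 in females only and 2741 at an adjusted p under 0.1. Alternatives chosen after seeing the data gave 4024 with sample weights and 953 with the spots in very high local background kept, 935 of them shared with the 1648. The main processing, which leaves those spots out, was itself adopted after the 953 had been seen. Leaving out replicates gave 372 to 3541 genes: 682 without control 1, 586 without control 2, 372 without control 3 (186 higher and 186 lower), 1053 without control 4, 3541 without deficient 2 and 486 without deficient 4. Leaving out arrays gave 904 without array 2, 208 without array 3 and 2864 without array 4. The lists numbered 10 to 13 with a replicate or array left out, 0 with an estimated correlation (smallest adjusted p 0.45 in camera, 0 at an unadjusted p under 0.05) and 28 in fry for change in either direction. Directional fry called 10, but not beta-oxidation, cell cycle or oxidative phosphorylation (fry adjusted p = 0.096, 0.0584 and 0.096), and added bile acids, the growth hormone axis and p53 targets (0.011, 0.0057 and 0.0399). For sex, limma called 11 genes with loess only, 3 on within-array ratios with a dye term and 120 with sample weights (added after seeing the data). Leaving out replicates or arrays gave 0 to 6639 genes for sex: 7 without control 1, 340 without deficient 2, 74 without array 1, and 6639 without deficient 1, which became 0 when the array correlation of the 8 samples was kept. The cause of the other differences was not tested. Over the 12 settings with a replicate or array left out, 39 of the 109 called named genes kept their call in all and 70 lost it in at least 1. Fst kept its call in 7, Hdc in 8, and Car3, Ces1d and Sez6 in 11, while the other 19 of the 24 largest changes kept theirs in all 12. Dim genes are limited by signal over background, with 59.1% to 65.5% of spots well above it.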

Other observations

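The selenoprotein test in this part was chosen after the results were seen. Of 14 circadian genes 11 were not called. Dbp rose by 1.38 ± 0.36 while Nr1d1 (-0.47 ± 0.11) and Bhlhe40 (-0.76 ± 0.16) fell, and Bmal1 was at -0.87 ± 0.25 (limma adjusted p = 0.0589), with no call for the list (camera adjusted p = 0.794). With a replicate or array left out, Dbp kept its call in 3 of 12 settings, Nr1d1 in 4 and Bhlhe40 in 5. Among drug-metabolising P450 genes Cyp2c7 (-1.37 ± 0.22), Cyp1a2 (-1.19 ± 0.30), Cyp2c22 and Cyp2d2 fell and Cyp2d3 (0.78 ± 0.18) rose (camera adjusted p = 0.213 for the list). Cyp2c7 kept its call in 11 of those settings, Cyp2c22 in 6, Cyp1a2 in 5, and Cyp2d2 and Cyp2d3 in 4. Of the pancreas markers, Spink1 was at 2.62 ± 0.82 (limma adjusted p = 0.0765), with ratios of -0.33, 1.82, 4.13 and 4.84 on arrays 1 to 4.

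Gpx1, a selenoprotein, fell by 1.90 ± 0.14, and transcripts of selenoproteins differ in how far they follow the supply of selenium. A lower selenium status is a possible explanation that would need the selenium-sensitive group to fall more than the resistant one. Over 6 sensitive genes other than Gpx1 and 8 resistant ones, the difference of the mean log2 fold changes was -0.307 (one-sided exact permutation p = 0.0453 over 3003 groupings). It was at or below the bound of -0.3 in only 6 of the 12 settings with a replicate or array left out, and over 31 settings it ran from -0.375 to -0.244. The requirement that it hold in those settings was added after these values were seen, and genes are not independent replicates, so this stays undecided.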
